A study of Mus musculus with 21 samples.

How the data were processed

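RNA was measured in 21 libraries of mouse bone marrow cells, from animals with a Stag2 knockout (KO) and from wild-type (WT) animals, in 3 sorted populations. LSK cells are stem and multipotent progenitor cells, GMP are granulocyte and monocyte progenitors, and CFU-E are erythroid progenitors. Per the labels' protocols, marrow was depleted of lineage-positive cells before the sort and RNA was extracted with TRIzol. Per the labels' protocols, LSK libraries were amplified over full transcripts with SMARTer, while GMP and CFU-E libraries were sequenced at their 3′ ends after SMART-Seq2 amplification. A 3′ tag reports only the end of a transcript, so a deletion elsewhere in a gene need not lower its count.

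The deposited values are whole-number counts per gene, 30733 genes by 21 libraries, with no normalization. Per the submitters' processing notes, the tools were STAR 2.4, HTSeq 0.6.1 and DESeq2, and the genome build was mm9. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, and members of families of near-identical copies (the globins, Stfa1, Ear1, Hspa1b, Ifitm1 and S100a8 among those named), are uncertain. The reference genome at hand is of another build and no coordinates were used. Of the 30733 genes, 82 had no count in any library, and no row lacked a gene name.

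Groups were taken from the labels: LSK KO (n = 3), LSK WT (n = 4), GMP KO (n = 4), GMP WT (n = 3), CFU-E KO (n = 4) and CFU-E WT (n = 3). The labels number the replicates but do not say that they came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. No pair of libraries in a group agreed within sampling noise: over genes with a summed count of at least 20, chi-square per degree of freedom was at least 4.03. The descriptions name a flow cell for GMP and CFU-E libraries. All GMP libraries, CFU-E KO 1, CFU-E WT 1 and CFU-E WT 2 share one flow cell, here A, and CFU-E KO 2, KO 3, KO 4 and WT 3 are on the other, here B.

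Each comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum count of 10 and minimum total count of 15, TMM factors, the quasi-likelihood F test, and Benjamini-Hochberg adjusted p under 0.05. KO was compared with WT within each population, with the flow cell as a term for CFU-E. The difference between 2 populations in the KO effect was tested as an interaction, with a flow cell term where CFU-E took part. WT CFU-E were also compared with WT GMP. LSK levels were not compared with the others because the library kits differ. Values are CPM scaled by TMM, as mean ± SD, and log2 fold changes carry their standard error (SE), which is the fold change divided by the square root of F.

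In all, 25 gene lists with 486 distinct members were fixed before the data were examined, of which 480 members are in the table; the other 6 were not analysed here. They cover cohesin and its regulators, HSC and self-renewal, Hox clusters A and B, lymphoid priming and early B, mature B and plasma cell, T and NK cell, myeloid regulators, primary granule and promyelocyte, late neutrophil, monocyte and macrophage, dendritic cell, MHC class II, erythroid regulators and membrane, heme synthesis and iron, globins, megakaryocyte and platelet, mast cell with basophil and eosinophil, interferon response, NF-kB and inflammation, S phase, G2/M phase, p53 response, immediate early and heat shock, Myc and ribosome biogenesis, and sex-linked genes. Of the members, 23 stand in more than 1 list. The sex-linked list served only as a check. Each list with at least 3 tested members was tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry.

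Genes were named by a rule also fixed before the data were examined. Stag2 and Stag1 are always given. Among genes past the threshold, with a mean of at least 5 CPM and no overlap between KO and WT libraries, the 8 largest rises and the 8 largest falls are eligible; symbols that start with Gm and a digit or end in Rik are counted only. Added to these are up to 4 members with the smallest p of each list called by camera, up to 2 members past the threshold of other lists, 5 genes per direction for an interaction, and 3 genes per list for 6 lineage lists in the WT comparison. Of the genes that the rule selects, 3 are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

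The tests were tried on simulated counts with 200 changed genes. In the LSK simulation of 17664 genes, edgeR called 0.0% of genes changed 1.5-fold, 19.4% of those changed 2-fold and 68.2% of those changed 4-fold. In GMP, over 9969 genes, the shares were 5.97%, 34.3% and 98.5%. In CFU-E, over 10170 genes, they were 14.9%, 53.7% and 92.4%. In the LSK simulation DESeq2 1.42.0 called 42 unchanged genes and edgeR 3.

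Alternatives were DESeq2 size factors, no filter on low counts, a stricter filter of at least 5 CPM in 3 libraries, the DESeq2 Wald test, limma-voom with sample quality weights, robust empirical Bayes, a replicate block, also across GMP and CFU-E, GMP counts thinned with a random draw to the depth of the shallowest library, models without the flow cell term or within 1 flow cell, and leaving out each library in turn.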

Results

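The study measured how loss of Stag2, a subunit of the cohesin ring that holds chromatin loops, alters transcription in stem and progenitor cells of the marrow. Total counts ran from 22813333 to 32196233 per LSK library, 1250683 to 4401993 per GMP library and 3654667 to 5550165 per CFU-E library. In GMP, depth went with genotype, from 1250683 to 3471881 in KO and from 3732769 to 4401993 in WT. GMP KO 1 was the shallowest library, and GMP KO 4 had the lowest mean correlation with its group, 0.928. All LSK libraries had high Xist and no excess of Y-linked transcripts, while GMP and CFU-E libraries had the male pattern, so sex did not differ between KO and WT within a population but did differ between LSK and the others.

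The targeted gene was examined first. Stag2 fell in LSK KO to 72.3 ± 6.61 CPM (SD, n = 3) from 166.1 ± 16.9 (n = 4) in WT, a log2 fold change of -1.20 ± 0.128 (SE, adjusted p = 0.027). In CFU-E it fell to 64.2 ± 15.7 CPM (n = 4) from 140.7 ± 17.7 (n = 3), a log2 fold change of -1.13 ± 0.205 (adjusted p = 0.0143). In GMP, Stag2 stood at 106.0 ± 30.4 CPM in KO (n = 4) and 147.3 ± 51.2 in WT (n = 3), with overlapping libraries (log2 fold change -0.47 ± 0.271, adjusted p = 0.36). GMP KO 4, at 150.2 CPM, lay above WT 2 and WT 3, at 143.1 and 98.28, so these values do not show the knockout in GMP. A 3′ tag outside the deleted part need not fall, but GMP and CFU-E libraries both report 3′ tags. In CFU-E, Stag2 was at 41.29 to 75.82 CPM in KO and 125.1 to 159.9 in WT. This argues against the position of the tag alone as the reason for the overlap in GMP. Stag1, the other form of this subunit, had log2 fold changes of 0.43 ± 0.128 in LSK, 0.57 ± 0.26 in GMP and 0.25 ± 0.171 in CFU-E, none past the threshold (adjusted p = 0.388, 0.266 and 0.7). The call of Stag2 ended in LSK without WT 3, WT 4, KO 1, KO 2 or KO 3 (adjusted p = 0.0657, 0.0681, 0.124, 0.151 and 0.132), with the replicate block (0.22) and without WT 2 and WT 4, chosen after seeing the data (0.0873). In each of these cases the log2 fold change in LSK stayed between -1.27 and -1.14. In CFU-E the call ended without WT 3 (0.703, log2 fold change -0.85), within flow cell A alone (0.0518, -0.86) and with the replicate block and the flow cell term together (0.0804, -1.08).

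**Figure D1:**
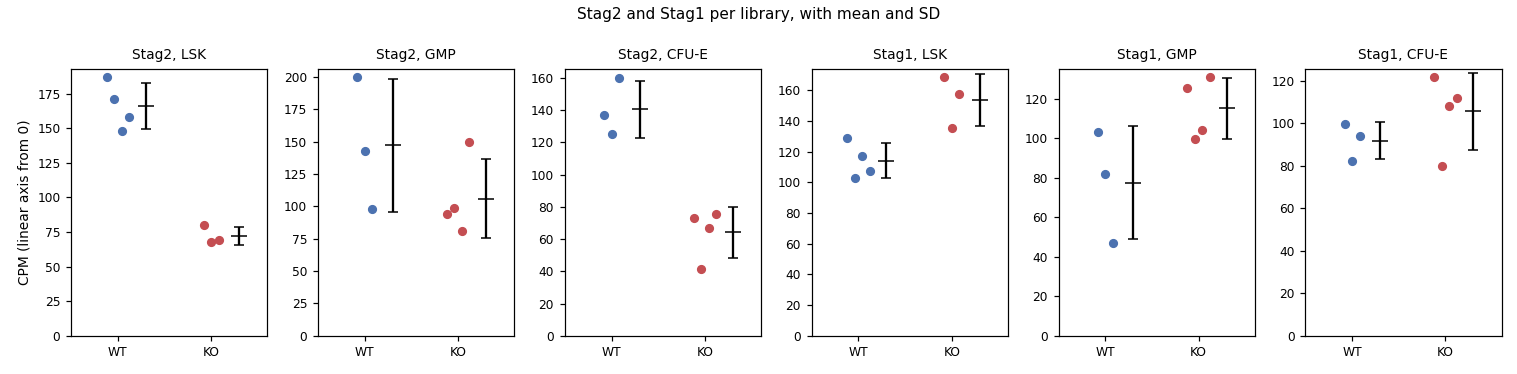
Stag2 and Stag1 in CPM (vertical axis, linear from 0) in each WT and KO library (points) of LSK, GMP and CFU-E, with the group mean and SD (bars). Stag2 separates KO from WT in LSK and CFU-E and overlaps in GMP, where the means are 106.0 and 147.3 CPM.

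In LSK cells, few genes passed the threshold. The simulated test called only 19.4% of genes changed 2-fold there, so few calls do not show that few genes changed. Cnn3, an actin-binding calponin, fell to 5.67 ± 0.979 CPM (SD, n = 3) from 27.0 ± 2.91 (n = 4), a log2 fold change of -2.25 ± 0.185 (adjusted p = 0.00851). Gria3, a glutamate receptor subunit, fell 3.04-fold, to 11.6 ± 1.01 CPM from 35.1 ± 2.33 (adjusted p = 0.00851), and the transporter Slc16a11 fell by 3.51 ± 0.349 on the log2 scale (adjusted p = 0.0186). Mc5r, a melanocortin receptor, fell 4.64-fold, Bzrap1 3.98-fold and Cbara1, a mitochondrial calcium uptake regulator, 1.98-fold (adjusted p = 0.0369, 0.0397 and 0.0397). D18Ertd653e rose 3.34-fold (adjusted p = 0.0349). The other rising genes, Nxph1, Nrxn2, Samd14 and Gm14964, and the falling genes Gm2a and Lypd6b were outside the naming rule and are named after their values were seen.

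The monocyte, lymphoid, mature B, granule, late neutrophil and MHC class II lists stood lower in LSK KO at the preset correlation of camera, and none of them was called with an estimated correlation. Of 21 tested monocyte and macrophage genes, 0 were called over all genes and 8 fell when adjusted over the list alone, with a median log2 fold change of -1.27 (camera adjusted p = 1.61e-14; adjusted p = 0.327 with an estimated correlation). Its members F13a1 and Ms4a6c had log2 fold changes of -1.19 ± 0.295 and -1.55 ± 0.38 (adjusted p = 0.268 and 0.264). Of 27 lymphoid priming and early B genes, 0 were called and 7 fell when adjusted over the list alone, with a median of -0.56 (camera adjusted p = 3.57e-08; adjusted p = 0.327 with an estimated correlation). Ebf1, a master regulator of B cell fate, stood at 1.09 ± 0.385 CPM in KO and 8.13 ± 4.2 in WT, and the cytokine receptor Flt3 at 129.1 ± 12.8 and 218.2 ± 39.7 (adjusted p = 0.146 and 0.206). Of the 27 members, 6 were positive, among them Dntt at 0.45 ± 0.197, named after its values were seen. Of 11 mature B and plasma cell genes, 0 were called and 6 fell when adjusted over the list alone, with a median of -1.73 (camera adjusted p = 6.56e-10; adjusted p = 0.327 with an estimated correlation). Cd22, Fcer2a and Faim3 had log2 fold changes of -2.62 ± 0.487, -2.97 ± 0.554 and -2.38 ± 0.393 (adjusted p = 0.155, 0.155 and 0.131). Of the 11 members, 4 were positive, among them Sdc1 at 0.73 ± 0.762 and Pou2af1 at 0.40 ± 0.81, both named after their values were seen.

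Of 19 primary granule and promyelocyte genes in LSK, 0 were called and 4 fell when adjusted over the list alone, with a median of -0.69 (camera adjusted p = 3.57e-08; adjusted p = 0.695 with an estimated correlation), among them the hexokinase Hk3 at -1.11 ± 0.22 (adjusted p = 0.175). Of 21 late neutrophil genes, 0 were called on either adjustment, adjusted over the list alone included, with a median of -1.24 (camera adjusted p = 0.000672; adjusted p = 0.731 with an estimated correlation). S100a8 differed widely among LSK WT libraries, with 2063 CPM before scaling in WT 2 and 1284 in WT 4, against 73.5 in WT 1 and 375.8 in WT 3. The MHC class II list had a median of -0.71 with 0 of 10 members positive (camera adjusted p = 0.000172; adjusted p = 0.701 with an estimated correlation). Hox clusters A and B had a median of -0.27 (camera adjusted p = 0.0284; adjusted p = 0.701 with an estimated correlation), and myeloid regulators -0.16 (camera adjusted p = 0.0302; adjusted p = 0.731 with an estimated correlation). The interferon response list had a higher median, 0.23 (camera adjusted p = 0.000647; adjusted p = 0.701 with an estimated correlation). So had immediate early and heat shock at 0.28 (camera adjusted p = 0.00262; adjusted p = 0.731 with an estimated correlation) and S phase at 0.16 (camera adjusted p = 0.021; adjusted p = 0.731 with an estimated correlation). No single gene of the MHC class II, Hox, interferon, immediate early or S phase lists was called over all genes or when adjusted over the list alone. Of 19 myeloid regulators, 0 were called and 2 fell when adjusted over the list alone. Calls ended without KO 2 for interferon response (adjusted p = 0.132, with the median at 0.11), immediate early and heat shock (0.438, median -0.05) and Hox (0.291, median -0.14). They ended without WT 2 for late neutrophil (0.244, with the median at -0.29), S phase (0.386, median 0.06) and Hox (0.117, median -0.26). Without KO 1 they ended for late neutrophil (0.0799, with the median at -0.94), S phase (0.18, median 0.15) and myeloid regulators (0.704, median 0.07). They also ended without WT 1 for Hox (0.108, median -0.29), without WT 3 for myeloid regulators (0.294, median 0.02), and without KO 3 for myeloid regulators (0.103, median -0.25) and S phase (0.0949, median 0.10). Without WT 2 and WT 4, an exclusion chosen after seeing the data, the median of late neutrophil turned to 0.33 (0.0776) and the call of MHC class II ended (0.465, median -0.34). Those of Hox (0.163, median -0.12), myeloid regulators (0.0776, median -0.30) and S phase (0.915, median 0.02) ended as well. Immunoglobulin transcripts took 0.532% to 7.79% of counts in LSK WT and 1.42% to 9.95% in LSK KO.

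Of 17664 genes tested in LSK, 5 rose and 9 fell. The count was 123 without WT 1, 9 without WT 2, 0 without WT 3, 4 without WT 4, 2 without KO 1, 0 without KO 2 and 4 without KO 3. In all, 1 gene passed without WT 2 and WT 4, an exclusion chosen after seeing the data. DESeq2 called 338 genes. Of the 8 genes named by the rule that passed, 8 lost the call without WT 3, 8 without KO 1, 8 without KO 2, 7 without KO 3, 5 without WT 4 and 2 without WT 2, with adjusted p from 0.0511 to 0.255.

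In GMP, single genes of the neutrophil lineage fell with the KO. Serpinb1a, an inhibitor of neutrophil serine proteases, fell to 264.7 ± 61.4 CPM (SD, n = 4) from 826.3 ± 87.5 (n = 3), a log2 fold change of -1.64 ± 0.231 (adjusted p = 0.00144). Ltf, the granule protein lactoferrin, fell to 681.2 ± 114 CPM from 1433 ± 200, a log2 fold change of -1.07 ± 0.218 (adjusted p = 0.0235). The largest falls were in Rasl11b (16.1-fold), the adhesion molecule Cdh1 (9.65-fold), Ifitm1 (9.01-fold), Bzrap1 (8.57-fold), Cenpv (7.61-fold), the matrix protein gene Fn1 (7.41-fold), Crispld2 (7.32-fold) and the secreted peroxidase Gpx3 (7.19-fold), with adjusted p between 1.43e-05 and 0.0162. Ifitm1, Cenpv, Rasl11b and Fn1 had KO means of only 1.235, 1.38, 1.74 and 2.035 CPM, so the size of these folds is poorly determined. Large rises were found in Stfa1, a cysteine protease inhibitor (to 8.76 ± 3.17 CPM from 0.791 ± 0.729), P2ry10 (6.01-fold), Tcf7l2 (5.26-fold), Pde5a (5.08-fold), H2afy2 (4.29-fold) and Sdr39u1 (3.94-fold), with adjusted p between 0.00764 and 0.0494.

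Of 18 late neutrophil genes in GMP, 2 fell (Ltf and Fpr2), 16 were not called, and 8 fell when adjusted over the list alone, with a median log2 fold change of -0.60 (camera adjusted p = 8.69e-05; adjusted p = 0.434 with an estimated correlation). Ngp and S100a8, abundant neutrophil transcripts, stood at 12240 ± 2880 and 47050 ± 13700 CPM in KO and 24580 ± 2770 and 96290 ± 12500 in WT (adjusted p = 0.0592 and 0.081). S100a8 was lowest in GMP KO 4, with 31850 CPM before scaling. Of 14 monocyte and macrophage genes, 1 fell (Fn1) and 5 fell when adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.0023; adjusted p = 0.241 with an estimated correlation). Klf4, Lgals3 and Ms4a6c had log2 fold changes of -1.05 ± 0.265, -0.93 ± 0.285 and -0.71 ± 0.221 (adjusted p = 0.0631, 0.122 and 0.129). Of 19 primary granule and promyelocyte genes, 2 fell (Serpinb1a and Hk3), the same number when adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0339; adjusted p = 0.501 with an estimated correlation). Of 5 MHC class II genes, 1 fell, Cd74 at -2.23 ± 0.504 (adjusted p = 0.0393), and 2 fell when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.0211; adjusted p = 0.434 with an estimated correlation). Of 16 immediate early and heat shock genes, 0 were called on either adjustment, adjusted over the list alone included, and 1 was positive, with a median of -0.46 (camera adjusted p = 0.00783; adjusted p = 0.434 with an estimated correlation). The call of the primary granule list ended without WT 3 (adjusted p = 0.159, with the median at -0.05) and without KO 4 (0.154, median -0.08). It also ended with the replicate block (0.137, median -0.09) and without KO 1 and KO 4, chosen after seeing the data (0.127, median -0.12). The call of MHC class II ended without WT 2 (0.0786, median -0.37), without WT 3 (0.0968, median -0.15) and with thinned counts (0.169, median -0.48).

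Single members of other lists rose in GMP KO. Tcf4, a transcription factor of plasmacytoid dendritic cells, rose to 140.1 ± 69.8 CPM from 43.3 ± 11.2 (adjusted p = 0.0162), and Gbp2, an interferon-induced GTPase, to 6.54 ± 1.15 from 1.32 ± 0.724 (adjusted p = 0.0242). Ear1, an eosinophil ribonuclease, rose to 53.2 ± 14.1 from 17.9 ± 10.6 (adjusted p = 0.0379) and Msi2, an RNA-binding protein of stem cells, to 53.7 ± 30.8 from 19.6 ± 2.48 (adjusted p = 0.0457). Of 9969 genes tested in GMP, 45 rose and 100 fell. The count was 43 without WT 2 (7 rose and 36 fell), 38 without WT 3 (2 rose and 36 fell) and 62 without KO 3 (18 rose and 44 fell). It was 110 without KO 1 and KO 4, and 67 with all libraries thinned to the depth of the shallowest, 64 of them among the 145; both settings were chosen after seeing the data. DESeq2 called 262 genes and limma-voom with sample quality weights 1264, of which 617 rose. Calls of genes named in GMP ended for 14 without WT 3, 13 without WT 2, 11 without KO 3, 8 without KO 2, 7 without WT 1 and 4 without KO 1, with adjusted p from 0.0518 to 0.285. Serpinb1a passed in each case, and Ltf lost its call without WT 2, WT 3, KO 1 or KO 3 (0.211, 0.0652, 0.0731 and 0.0797).

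**Figure D2:**
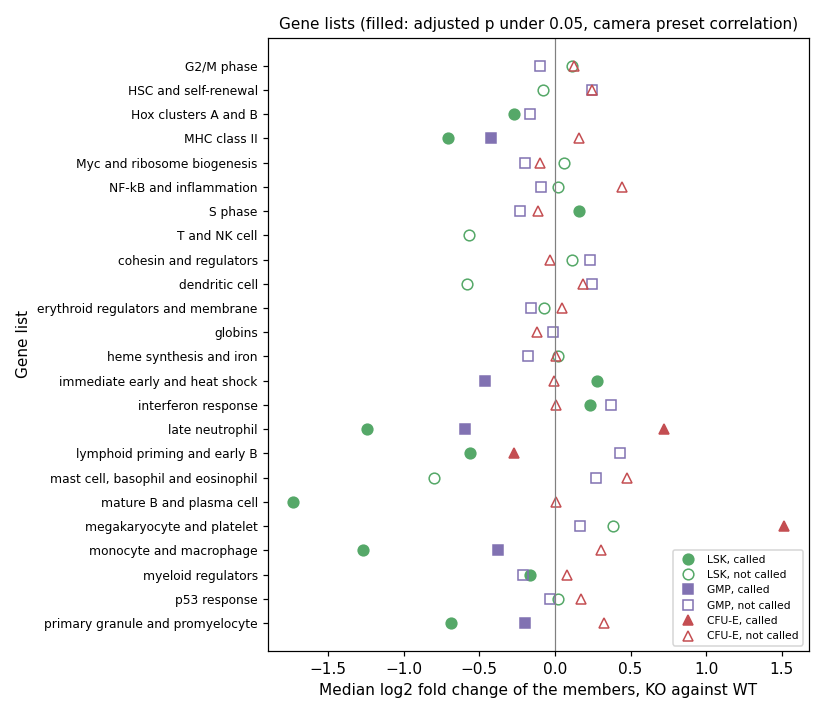
Median log2 fold change, KO against WT (horizontal axis), of the tested members of each gene list (vertical axis) in LSK (circles), GMP (squares) and CFU-E (triangles). Filled symbols have a camera adjusted p under 0.05 at the preset correlation, the highest being the megakaryocyte and platelet list in CFU-E at 1.51.

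In CFU-E, megakaryocyte and platelet genes stood higher in the KO. Of 18 tested members of that list all 18 were positive and 6 rose, 14 when adjusted over the list alone, with a median log2 fold change of 1.51 (camera adjusted p = 3.18e-25; adjusted p = 0.267 with an estimated correlation). Plek, the platelet kinase substrate pleckstrin, rose to 69.6 ± 15.2 CPM (SD, n = 4) from 20.6 ± 6.55 (n = 3), a log2 fold change of 1.66 ± 0.256 (adjusted p = 0.00468). The integrins Itgb3 and Itga2b, which form the platelet fibrinogen receptor, rose to 42.1 ± 11 and 168.0 ± 61.3 CPM from 12.1 ± 4.63 and 54.9 ± 16 (adjusted p = 0.0061 and 0.0163). The platelet chemokine Ppbp rose 10.9-fold (adjusted p = 0.0128). Its call ended without WT 3 (adjusted p = 0.18), without KO 1 (0.143) and with limma-voom (0.0787). With robust empirical Bayes the calls of Ppbp and Itga2b both ended (adjusted p = 0.206 and 0.137). The list's median was 1.29 within flow cell A and 1.65 within flow cell B.

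The largest falls in CFU-E KO were in Cnn3, to 0.938 ± 0.419 CPM from 30.9 ± 0.885 (log2 fold change -5.10 ± 0.33, adjusted p = 2.78e-06), Gna14, a G protein subunit (30.6-fold), Nags (14.2-fold), Parm1 (13.4-fold), the ubiquitin ligase Rnf128 (11.5-fold), Pde3b (9.39-fold), Cecr2 (8.80-fold) and Enpp1 (8.50-fold), with adjusted p up to 0.0287. Gna14, Parm1, Nags and Pde3b had KO means of only 0.502, 1.18, 1.355 and 1.43 CPM, so the size of these folds is poorly determined. The largest rises, apart from Ppbp, were in F11r, a junction adhesion molecule (to 9.69 ± 5.77 CPM from 0.428 ± 0.304), Plxna2 (10.3-fold), Esam, an adhesion molecule of stem cells and megakaryocytes (5.45-fold), Nkx1-2 (5.01-fold), Actn1 (4.21-fold), the fatty acid transporter Cd36 (4.19-fold) and Ly9 (4.13-fold), with adjusted p up to 0.0356.

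Of 35 erythroid regulator and membrane genes, 0 were called on either adjustment, adjusted over the list alone included, with a median of 0.04 (camera adjusted p = 0.933). Of 4 globin genes, Hbb-b1 fell to 115.3 ± 19.6 CPM from 308.5 ± 55.2, a log2 fold change of -1.39 ± 0.177 (adjusted p = 0.00113). Its near-identical neighbour Hbb-b2 stood at 898.2 ± 227 and 572.9 ± 84.2 (log2 fold change 0.72 ± 0.196, adjusted p = 0.122), and reads shared between these copies make both values uncertain. The early response genes Jun and Jund fell by 1.36 and 1.30 on the log2 scale (adjusted p = 0.0109 and 0.0135). Of 10 late neutrophil genes, 0 were called, 3 rose when adjusted over the list alone, and all 10 were positive, with a median of 0.72 (camera adjusted p = 0.000207; adjusted p = 0.408 with an estimated correlation). Ngp stood at 119.7 ± 50.9 CPM in KO and 59.6 ± 15.1 in WT (adjusted p = 0.0735). Of 7 lymphoid priming and early B genes, 1 fell (Cecr2), and 3 fell and 1 rose when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.00447; adjusted p = 0.267 with an estimated correlation). Cecr2 encodes a chromatin remodelling factor that is not specific to B cells, and the member with the higher value was Foxo1, at 21.1 ± 2.24 CPM in KO and 12.1 ± 3.33 in WT (adjusted p = 0.0698). The call of the late neutrophil list ended without KO 1 (adjusted p = 0.0724, with the median at 0.70) and that of the lymphoid list without WT 3 (0.0534, median -0.54).

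Of 10170 genes tested in CFU-E, 36 rose and 72 fell. The count was 22 without WT 3 (7 rose and 15 fell), 53 without KO 1 (4 rose and 49 fell) and 234 without the flow cell term (99 rose and 135 fell). Within flow cells it was 130 in A (KO n = 1, WT n = 2) and 82 in B (KO n = 3, WT n = 1), where the lone library is assumed to vary like the rest. DESeq2 called 164 genes. Calls of named genes ended for 17 without WT 3, 14 without KO 1, 3 without WT 1, 2 without KO 3 and 1 without WT 2. Among them were Plek, Itgb3 and Itga2b without WT 3 (adjusted p = 0.207, 0.15 and 0.361) or KO 1 (0.0589, 0.0974 and 0.118) and Hbb-b1 without WT 3 (0.201).

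**Figure D3:**
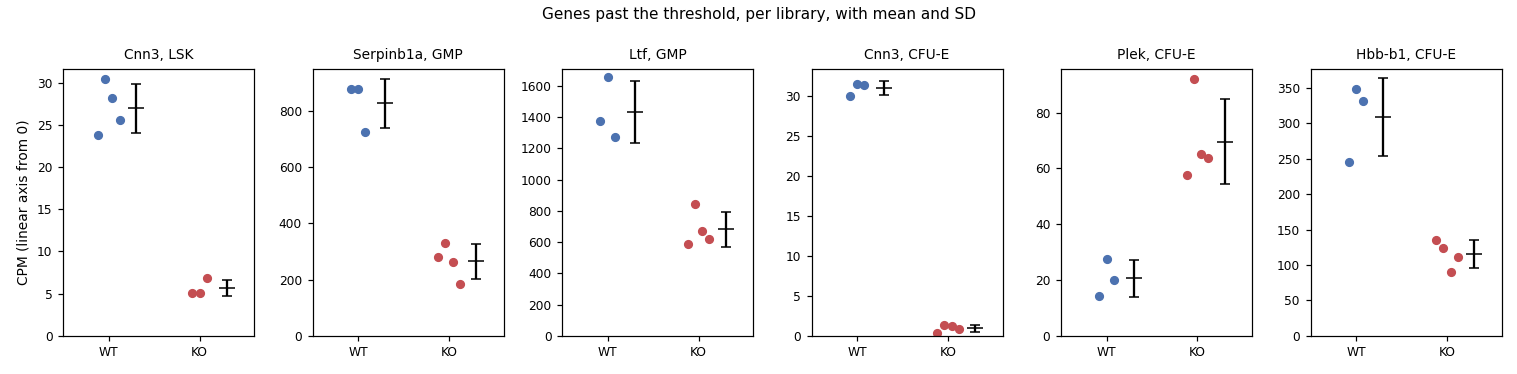
CPM (vertical axis, linear from 0) in each WT and KO library (points) for Cnn3 in LSK, Serpinb1a and Ltf in GMP, and Cnn3, Plek and Hbb-b1 in CFU-E, with group mean and SD (bars). The KO and WT libraries of each gene shown do not overlap; Cnn3 in CFU-E has a KO mean of 0.938 CPM and a WT mean of 30.9.

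The KO effect was then compared between populations. It differed between CFU-E and GMP for 49 of 11006 genes, 37 with a higher log2 fold change in CFU-E and 12 with a lower one. Actn1, an actin cross-linker, rose in CFU-E by 2.07 ± 0.359 on the log2 scale and fell in GMP (log2 fold change -1.33 ± 0.2), a difference of 3.48 ± 0.351 (adjusted p = 2.95e-05). Differences in the same direction were found for Rhoj (4.95), Tspan14 (2.75), Ptgs1, which makes prostaglandins (2.28), and Sla (2.25), and in the other direction for Rnf128 (-3.74), Enpp1 (-3.13), Gda (-2.68), Chst11 (-2.34) and the calcium pump Atp2b4 (-1.95), with adjusted p up to 0.00238. The count was 28 without GMP WT 2, 31 without CFU-E WT 1, 2 without CFU-E WT 3, 16 without CFU-E KO 1, and 2 within flow cell A. DESeq2 called 141 genes. Of the 10 genes named, 8 lost the call without CFU-E WT 3 (adjusted p from 0.0526 to 0.267), while Actn1 and Enpp1 passed.

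LSK libraries differ from those of CFU-E and GMP in sex and in library kit as well as in population. A difference in the KO effect between LSK and either one cannot be assigned to the population alone. Between LSK and CFU-E, 7 of 16474 genes differed. Cnn3 fell in both populations, by 2.83 ± 0.387 less on the log2 scale in LSK (adjusted p = 0.0207). Tsc22d1 had a log2 fold change of 0.86 ± 0.135 in LSK and fell in CFU-E (-1.38 ± 0.163), a difference of 2.19 ± 0.212 (adjusted p = 0.000542). The differences were 4.29 for Gna14 and 2.42 for Mboat2, and -2.90 for Tpm4, -2.85 for Actn1 and -1.84 for Tspan14 (adjusted p between 0.0207 and 0.0263). The count was 24, 11, 1 and 12 without LSK WT 1, 2, 3 and 4, 3, 4 and 1 without LSK KO 1, 2 and 3, 1 without CFU-E WT 1, 1 without CFU-E WT 3 and 2 without CFU-E KO 1. DESeq2 called 88 genes. Of the 7, only Tsc22d1 passed without each library in turn. Between LSK and GMP, edgeR called 0 of 16288 genes, with 1732 at an unadjusted p under 0.05, and DESeq2 called 71; edgeR called 8 without GMP KO 1 and 3 without GMP KO 3.

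Effects in different populations shared single genes. LSK and GMP shared 4 falling genes of 6 and 100 called, against 0.0613 from independent lists (Fisher's exact test, one-sided, p = 1.51e-07): Cnn3, Cbara1, Gm2a and Bzrap1, and 1 rising gene, D18Ertd653e. LSK and CFU-E shared the fall of Cnn3, besides that of Stag2, which was knocked out in both. GMP and CFU-E shared the falls of Cnn3, Aplp2, Cenpv and Ly6e, against 0.213 (exact p = 5.65e-05), and the rises of Pde5a and Eps8l1, against 0.0771 (exact p = 0.00263). With the stricter filter only Pde5a of these rises was shared (exact p = 0.0688), and Cnn3 was no longer among the shared falls of GMP with LSK (3 shared, exact p = 9.25e-06) or with CFU-E (3 shared, exact p = 0.000295). Those shared genes outside the naming rule were named after their values were seen. Across genes, which are not independent replicates, log2 fold changes correlated with Pearson r = 0.273 and Spearman rho = 0.165 between LSK and GMP. They were 0.133 and 0.0518 between LSK and CFU-E, and 0.00343 and -0.0457 between GMP and CFU-E.

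WT CFU-E were compared with WT GMP to check the sorted populations. Of 10329 genes, 2587 were higher in WT CFU-E and 2822 higher in WT GMP (5037 in all within flow cell A). Add2 and Epb4.2 of the red cell membrane skeleton and the carbonic anhydrase Car1 were 166-fold, 150-fold and 115-fold higher in CFU-E, and the heme genes Cpox and Steap3 were 18.1-fold and 13.4-fold higher, with Hebp1 at 99.2 ± 5.09 CPM in CFU-E and 7.09 ± 3.47 in GMP. The globin genes Hbb-b1, Hbb-b2 and Hba-a1 were 11.4-fold, 10.6-fold and 6.45-fold higher. Fcnb, Ctsg and Prtn3 of primary granules were 706-fold, 678-fold and 629-fold higher in GMP, Camp, S100a8 and S100a9 of late neutrophils 610-fold, 571-fold and 537-fold higher, and Vcam1, Mpeg1 and F13a1 of monocytes 337-fold, 196-fold and 180-fold higher. Adjusted p was at most 1.14e-06 for these 18 genes.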

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

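The tests of explanations in this part were chosen after the result was seen, except the splits of the libraries.

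Single libraries stood apart from the other 3 of their group for 7 of 123 gene and group pairs, where chance gives about 1 in 20. Gfi1 was at 93.7 CPM in GMP KO 4 and 145 to 151 in the others, and Tcf4 at 245 in GMP KO 4 and 98.1 to 112. Cecr2 was at 5.10 CPM in CFU-E KO 1 (1.86 to 2.13 in the others), Foxo1 at 24.5 in CFU-E KO 1 (19.8 to 20.2) and F11r at 18.3 in CFU-E KO 2 (6.19 to 7.34). Ddx58 was at 64.9 CPM in LSK WT 1 (49.3 to 50.4) and Hspa1b at 748 in LSK WT 2 (429 to 478).

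The KO effect differed between CFU-E and GMP, by a test of the difference, for Actn1 (3.48 on the log2 scale), Rhoj (4.95), Tspan14 (2.75), Ptgs1 (2.28), Sla (2.25), Rnf128 (-3.74), Enpp1 (-3.13), Gda (-2.68), Chst11 (-2.34) and Atp2b4 (-1.95). Between LSK and CFU-E, which also differ in sex and library kit, it differed for Gna14 (4.29), Cnn3 (2.83), Mboat2 (2.42), Tsc22d1 (2.19), Tpm4 (-2.90), Actn1 (-2.85) and Tspan14 (-1.84).

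Other splits of the same libraries were fitted in the same way. In GMP, 1 of 35 splits, the real one, gave 145 genes or more and the highest other gave 17. In CFU-E, 1 of 34 splits, the real one, gave 108 or more and the highest other gave 84. The split by flow cell could not be fitted with the flow cell term. Each is the smallest share that so few splits can give, and it was not corrected for the number of comparisons. Chance is thus made less likely in GMP and CFU-E but is not excluded. In GMP the real split also separates the libraries by depth, which the splits cannot tell from genotype. In LSK, 3 of 35 splits gave 14 genes or more, so chance is not excluded; the split of KO 1, WT 2 and WT 4 from the rest gave 1562, which points to a structure of the LSK libraries other than genotype. For CFU-E against GMP, 2 of 38 drawn splits gave 49 genes or more, so chance is not excluded; the other one, also with 49, kept the GMP groups and nearly exchanged the CFU-E groups. For LSK against CFU-E, 1 of 40 drawn splits gave 7 or more and the highest other gave 3. The drawn splits exchange genotype within both populations. This share, the smallest that these splits can give, therefore bears only on the absence of a KO effect in either population. Whether equal KO effects could give this count was not tested. For LSK against GMP the real count was 0, so splits do not test it. The 10 splits of the WT comparison are too few for a share under 0.05; the real split gave 5409 genes and the highest other 0.

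For camera at the preset correlation, 12 of 35 splits gave at least the real 11 lists in LSK (highest other 17), 10 of 35 at least 5 in GMP (highest other 8) and 25 of 34 at least 3 in CFU-E (highest other 7). Chance is not excluded for the number of lists in any population.

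Lymphoid and early B genes stood lower in LSK KO, with a median log2 fold change of -0.56. The difference did not rest on LSK WT 2 and WT 4, the libraries with the most neutrophil transcripts, since the median was -0.64 without both. Mature B cells in the WT sorts, which the lineage depletion and the LSK gate should remove, remain a candidate explanation: the mature B and plasma cell list, with no member in common, had a median of -1.73, and of -1.08 without WT 2 and WT 4. The abundant B cell transcripts Ighm and Igkc had log2 fold changes of 0.94 ± 0.986 and 0.07 ± 0.801. These errors are too wide to decide on a simple carry-over, and plasma cell RNA could also hide a B cell share there. A genotype effect on lymphoid priming stays open and was not separated from a change in cell content.

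Megakaryocyte and platelet genes stood higher in CFU-E KO. The flow cell as the whole cause is argued against by medians of 1.29 and 1.65 within flow cells A and B. The neutrophil, monocyte and granule lists together had a median of 0.504, a gap of 1.01 (95% bootstrap interval over genes 0.553 to 1.35). That interval treats genes that move together as independent and does not measure the spread between libraries. The gap bears only on a lower share of erythroid cells that raises every other lineage alike. A lower share with an uneven rise stays open. Platelets or megakaryocyte-lineage cells among the sorted cells, which a CFU-E sort should remove, may account for the higher megakaryocyte and platelet genes. The markers of that sort are not given in the sources used here. Of 12 platelet transcripts chosen outside the list, 8 entered the test, with a median of 1.34 and 6 positive. Tubb1, Sparc, Myl9 and Alox12 did not enter it, so the median leaves them out. F5 and Cald1, at 1.17 and 1.64 CPM in WT and 7.43 and 5.9 in KO, may have entered only through their KO level, which would raise the median. Nrgn and Stom had negative values, -0.39 ± 0.214 and -0.32 ± 0.172. The median therefore does not decide whether such cells were present. Pf4, the most abundant member of the list, stood at 335.6 ± 145 CPM in KO and 98.5 ± 49.1 in WT. A megakaryocyte programme within KO erythroid progenitors would give the same values and stays open.

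Hbb-b1 was low relative to Hbb-b2 in CFU-E KO, with count ratios of 0.113 to 0.174 per library against 0.514 to 0.55 in WT. For these 2 genes, a globin gene variant carried by the KO animals is argued against by GMP, where the pooled KO ratio was 1.09 times the WT ratio. This holds if the GMP and CFU-E animals share a background, which the labels do not say. The summed counts had a log2 fold change of 0.27 ± 0.191, which is not distinguished from 0. Reads moved between the near-identical copies would leave the sum unchanged, but so would a change in the choice of globin gene. The sum therefore does not decide between these 2, and moved reads stay open. LSK ratios, from 42 Hbb-b1 counts in KO and 231 in WT, were lower in KO as well, at 0.0463 to 0.0617 per library. In LSK WT 1 to 3 they were 0.256 to 0.529, and 2.01 in WT 4, which held 137 of the WT counts. The ratio of Hba-a1 to Hba-a2 was lower in KO too, at 1.43 to 1.98 per CFU-E library against 3.93 to 5.05 in WT. In GMP it was 0.5 to 1.7 in KO and 1.86 to 2.92 in WT, from only 3 to 38 Hba-a1 counts per library. The explanations above were not tested on the alpha globins. A genotype effect on the choice of globin gene also stays open.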

How the results depend on the processing

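The exclusions of LSK WT 2 and WT 4, and of GMP KO 1 and KO 4, the thinned GMP counts and the replicate block across populations were chosen after seeing the data; the other settings were planned before the data were examined. The cause of each change below was not tested, except that leaving out libraries leaves fewer samples. WT CFU-E against WT GMP stayed within 1.5 times of 5409 under every setting tried, with 4731 to 5740 genes when a library was left out.

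Without a filter on low counts the calls were 38 in LSK, 601 in GMP (315 rose and 286 fell, 47.6% falling against 69.0%), 333 in CFU-E (44.1% falling against 66.7%), 254 for CFU-E against GMP, 12 for LSK against GMP and 32 for LSK against CFU-E. The DESeq2 Wald test gave 338, 262, 164, 141, 71 and 88 in that order. Limma-voom gave 22 in LSK and 1264 in GMP. Without the flow cell term CFU-E gave 234 genes, and CFU-E against GMP gave 2 within flow cell A. Without LSK WT 2 and WT 4, LSK gave 1 gene. With counts thinned to the shallowest library GMP gave 67 genes, 64 of them among the 145, and 4 lists, and H2-Ab1, not called in either, turned to 0.001927. Thinning also lowers the power of the test. Leaving out each library in turn gave 0 to 123 genes in LSK, 38 to 211 in GMP, 22 to 143 in CFU-E, 2 to 72 for CFU-E against GMP, 0 to 8 for LSK against GMP and 1 to 24 for LSK against CFU-E.

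Camera called 11 lists in LSK, 5 in GMP and 3 in CFU-E; with an estimated correlation it called 0 in each (3, 1 and 2 at an unadjusted p under 0.05), and fry called 0 in LSK, 1 in GMP (monocyte and macrophage, adjusted p = 0.00944) and 1 in CFU-E (lymphoid priming and early B, adjusted p = 0.049). Without LSK WT 2 and WT 4, 6 LSK lists were called, without GMP KO 1 and KO 4, 8 GMP lists, and without the flow cell term 5 CFU-E lists. Left-out libraries gave 8 to 14 lists in LSK, 4 to 8 in GMP and 3 to 5 in CFU-E. Without LSK WT 2 and WT 4, the late neutrophil list in LSK turned to a median of 0.33, S100a9 to 0.11 and Mmp8 to 0.15. With the stricter filter Pearson r was 0.105 for LSK and CFU-E and -0.0258 for GMP and CFU-E, which turned its sign.

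Replicate numbers were not found to pair libraries. Correlations of same-numbered deviations were 0.108, 0.0723 and 0.00324 in LSK, -0.157, 0.164 and 0.24 in GMP and 0.182, 0.254 and -0.183 in CFU-E, and not every library correlated best with its own number. With the replicate block the calls were 0 in LSK (902 at an unadjusted p under 0.05), 325 in GMP and 168 in CFU-E, and 31 in CFU-E with the block and the flow cell term together, where 6 lists were called. GMP and CFU-E libraries also carry the same numbers in the same genotypes, and the labels do not say whether these mark shared animals. Across these populations same-numbered deviations correlated at -0.129, -0.0829 and -0.182 in WT and at 0.0324, 0.109, 0.086 and 0.0896 in KO, so the numbers were not taken as pairs, and not every library correlated best with its own number. With the replicate block across populations CFU-E against GMP gave 32 genes, 25 of them among the 49, and all 10 named genes passed.

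Among settings other than a left-out library, named genes lost their call in 16 instances in LSK, 7 in GMP and 33 in CFU-E. With a library left out they did so in 38, 57 and 37 instances.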

Other observations

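With camera adjusted p from 0.0766 to 0.514, lists not called in LSK had medians of 0.11 for cohesin and regulators, -0.08 for HSC and self-renewal, -0.57 for T and NK cell, and -0.58 for dendritic cell. They were -0.07 for erythroid regulators, 0.02 for heme synthesis, 0.38 for megakaryocyte and platelet, and -0.80 for mast cell, basophil and eosinophil. They were 0.02 for NF-kB, 0.11 for G2/M phase, 0.02 for p53 response and 0.06 for Myc and ribosome biogenesis. Within the LSK megakaryocyte list, 7 members rose and 5 fell when adjusted over the list alone and 0 were called over all genes. In GMP, with camera adjusted p from 0.0851 to 0.855, they were 0.23 for cohesin and regulators, 0.25 for HSC and self-renewal, -0.17 for Hox clusters, 0.43 for lymphoid priming and early B, and -0.21 for myeloid regulators. Medians were 0.25 for dendritic cell, -0.16 for erythroid regulators, -0.18 for heme synthesis, -0.01 for globins, 0.16 for megakaryocyte and platelet, and 0.27 for mast cell, basophil and eosinophil. Medians were 0.37 for interferon response, -0.09 for NF-kB, -0.23 for S phase, -0.10 for G2/M phase, -0.03 for p53 response and -0.20 for Myc and ribosome biogenesis. In CFU-E, with camera adjusted p from 0.121 to 0.933, they were -0.03 for cohesin and regulators, 0.24 for HSC and self-renewal, 0.01 for mature B and plasma cell, 0.08 for myeloid regulators, and 0.33 for primary granule. Medians were 0.30 for monocyte and macrophage, 0.18 for dendritic cell, 0.16 for MHC class II, 0.01 for heme synthesis, -0.12 for globins, and 0.47 for mast cell, basophil and eosinophil. Medians were 0.01 for interferon response, 0.45 for NF-kB, -0.11 for S phase, 0.12 for G2/M phase, 0.17 for p53 response, -0.00435 for immediate early and heat shock and -0.10 for Myc and ribosome biogenesis. Lists with under 3 tested members in a population were not tested there. The median and the camera direction differed in sign for 3 lists in LSK (erythroid, NF-kB and p53) and 3 in CFU-E (mature B, myeloid regulators and erythroid), and the mean and the median differed in sign for NF-kB and p53 in LSK and for mature B, myeloid regulators and dendritic cell in CFU-E.

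Of 12 platelet transcripts outside the fixed list, chosen after the megakaryocyte list was seen, 8 were tested and 3 rose in CFU-E KO. The clotting factor gene F5 rose to 7.43 ± 2.37 CPM from 1.17 ± 1.36, Ctla2a to 14.5 ± 3.14 from 4.64 ± 1.38 and Rgs18 to 29.3 ± 2.21 from 15.0 ± 1.92 (adjusted p = 0.0392, 0.028 and 0.0426). Nrgn and Stom had log2 fold changes of -0.39 ± 0.214 and -0.32 ± 0.172 (adjusted p = 0.613 and 0.603).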
